A study of Mus musculus with 12 samples.

How the data were processed

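RNA sequencing values of 12 libraries of cultured mouse adipocytes were used, in 6 groups of 2: WT and KO-labelled inguinal preadipocytes differentiated with rosiglitazone (beige) or without it (white), and C3H10T1/2 cells with rosiglitazone as control or with ATF7 overexpressed. Groups were taken from the sample labels. Per the labels' protocols, RNA was extracted with TRIZOL, ribosomal RNA was depleted, directional libraries were made and 36 bases were read from both ends of each fragment. The FPKM values were made by the authors before they were deposited, 1 value per gene, per the file headers. They were placed on mm10 per the submitters' processing notes. The aligner, the quantifier, the annotation and any filter are not given in the sources used here. Reads and counts were not analysed here, so the depth of each library is unknown and no interval for counting error could be given.

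Each library had 24888 entries with 24341 distinct symbols. For the 830 entries whose symbol stands at more than 1 locus, the locus with the highest mean was used in the gene lists. The fits tested each entry on its own, so counts of genes are counts of entries. In 27 symbols a spreadsheet had turned the name into a date. There were 0 entries on the mitochondrial chromosome. Starts were counted from 0 in the deposited values: of 23446 genes with the same name in RefSeq, 61.0% had a start greater by 1 and 3.1% an equal start, so 1 was added to each start printed. An exact 0 may be a failed estimate and not a lack of reads. Genes at 0 in a whole group are therefore given as listed at 0, with no fold change, except that the closing section gives their fitted differences between cultures, which depend on the pseudocount. Paralogues, pseudogenes and histone copies may share reads, which makes Gapdh, some ribosomal protein genes, the MHC genes and the histone genes uncertain.

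Because the values were FPKM and not counts, the test fixed for normalized values was used: limma 3.58.1 (eBayes with trend) in R 4.3.3 on log2(FPKM + 1), for genes with at least 1 FPKM in at least 2 libraries of the fit, with Benjamini-Hochberg adjusted p under 0.05. The 8 libraries of primary cultures were fitted together, with 1 coefficient per group, 11294 genes and 4 residual degrees of freedom. The 4 libraries of C3H10T1/2 were fitted on their own, with 9981 genes and 2 residual degrees of freedom. Comparisons were KO-labelled against WT in beige and in white, beige against white in WT and in KO-labelled cultures, the interaction of genotype and rosiglitazone, and overexpression against control. Tests were two-sided. Agreement between effects was measured with Spearman's rho across genes and with the overlap of calls against the number expected if calls were independent. The tests, the gene lists, the naming rule and most alternative settings were chosen before the data were examined.

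Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and with an estimated correlation and with fry as alternatives. With an estimated correlation, camera also uses only the residual degrees of freedom of the fit, so few lists can pass. There were 46 lists with 1152 members, of which 1134 were matched, 4 of them by a synonym, and a list needed at least 3 tested members. The lists covered ATF2 and CREB relatives, H3K9 methyltransferases, adipocyte core genes, early adipogenic regulators, thermogenic genes, beige-selective and white-selective markers, PPARγ targets, lipogenesis, cholesterol synthesis, fatty acid oxidation, nuclear-encoded and mitochondrially encoded respiratory genes and the TCA cycle. They also covered interferon-stimulated genes, MHC class I, NF-κB, preadipocyte markers, extracellular matrix, TGF-β, Wnt, cell cycle, replication-dependent histones, p53, the integrated stress response, the unfolded protein response, NRF2, heat shock, immediate early genes, and hypoxia with glycolysis. Others were osteogenic, chondrogenic and skeletal muscle genes, markers of macrophages, lymphoid and mast cells, endothelium, pericytes, epithelium, mesothelium, Schwann cells and erythroid cells, housekeeping controls, ribosomal proteins, Hox genes, protocadherin clusters, and adipokines. List members were counted by the p adjusted over all genes tested and also adjusted over the list alone.

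Genes were named by a rule. In each comparison of genotype or dose, and in WT beige against white, it took the 6 largest rises and the 6 largest falls among called genes with a mean log2 value of at least 1 and no overlap of the groups, leaving out predicted genes, pseudogenes and small RNA genes. It added up to 4 members of each list with the lowest p, and the fixed genes Atf7, Ucp1, Cidea, Ppargc1a, Prdm16, Dio2, Pparg, Cebpa, Cebpb, Adipoq, Fabp4, Lep, Irf7, Isg15, Actb, Gapdh, Tbp and Rplp0. Dio2 did not pass the filter in either fit. Some genes that the rule takes up are not reported here.

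The test was tried on simulated values made from the real means and spread, in 5 runs with 200 changed genes each. Changed genes were drawn from those with a mean of at least 5 FPKM, and the spread was drawn separately for each gene. The recovery therefore does not cover genes of lower values, and the share of false calls does not cover genes that vary together between libraries. For KO-labelled against WT beige, over 10825 genes, 87.2% of genes changed 2-fold and 97.2% of those changed 4-fold were recovered, and 4.95% of calls were false. For overexpression, over 9975 genes, the values were 82.6%, 96.2% and 3.35%. Alternatives were another pseudocount of 0.1, no filter, quantile normalization, median centring, no trend, all 12 libraries in 1 fit, only the groups of the comparison, a replicate block, and each library left out in turn. Leaving out small RNA genes, and quantile normalization for the agreement of effects, were chosen after seeing the data. Where a group was left with 1 library, that library was assumed to vary like the other groups. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.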

Results

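Gene expression was measured by RNA sequencing in 12 libraries of cultured mouse adipocytes, in 6 groups of 2. In 8 libraries, preadipocytes from the inguinal fat of C57BL/6 mice, either wild type (WT) or labelled as lacking the transcription factor ATF7 (KO-labelled), were differentiated with rosiglitazone into beige adipocytes or without it into white adipocytes. Rosiglitazone is an agonist of the nuclear receptor PPARγ. The other 4 libraries came from C3H10T1/2, a mouse mesenchymal stem-like cell line that can form adipocytes, differentiated with rosiglitazone as a control or with ATF7 overexpressed. Values were FPKM (fragments scaled to transcript length and library size), so the read depth of each library is unknown and no counting interval is given. Between 9844 and 10877 genes per library reached 1 FPKM. The summed FPKM of a library lay between 225536 and 272371. Replicates of a group correlated across genes at a Pearson's r of 0.977 to 0.986 on log2 values, and genes are not independent replicates. Nothing in the labels says whether replicates were separate cultures or animals, so every p-value measures only the spread between these samples, which may be technical. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

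The targeted gene, Atf7 (chromosome 15, 102525946 to 102625464, mm10), was not lower in the KO-labelled libraries. In beige adipocytes it stood at 7.80 and 7.83 FPKM in WT and at 7.26 and 7.94 FPKM in KO-labelled libraries (log2 fold change −0.04, SE 0.12, adjusted p = 0.949). In white adipocytes the values were 9.10 and 7.10 FPKM in WT and 6.88 and 7.73 FPKM in KO-labelled libraries (−0.13, SE 0.12, adjusted p = 0.604). A value per gene does not show which exons were read, so it neither checks nor contradicts a deletion of part of the gene. Every direction given for the KO-labelled libraries rests on their labels alone. In C3H10T1/2, Atf7 rose from 8.52 and 9.09 FPKM in the controls to 41.2 and 39.1 FPKM in the overexpressing libraries (2.07, SE 0.07, adjusted p = 0.000162).

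**Figure D1:**
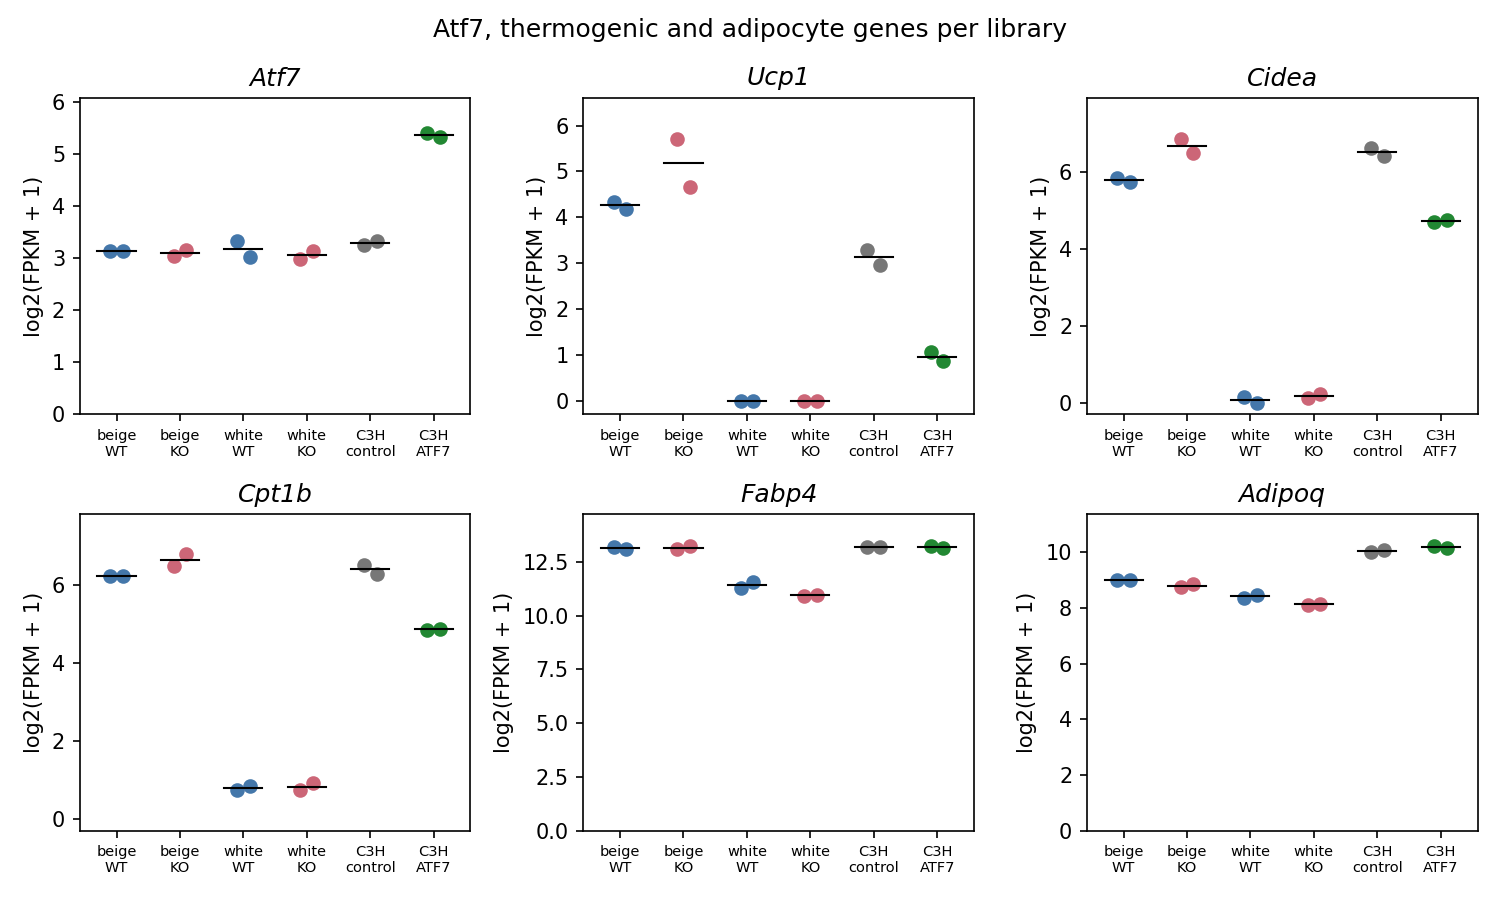
Values of Atf7, Ucp1, Cidea, Cpt1b, Fabp4 and Adipoq in each of the 12 libraries, as log2(FPKM + 1). Points are libraries and bars are the means of the 2 libraries of a group. Atf7 is higher in the overexpressing libraries, at 41.2 and 39.1 FPKM, than in their controls, at 8.52 and 9.09 FPKM.

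The comparison of WT beige with WT white adipocytes shows what the cultures with rosiglitazone expressed before the genotype is considered. Thermogenic genes rose: 26 of 30 tested members were higher in beige and 0 were lower (median log2 fold change 2.27). Ucp1, the uncoupling protein of the inner mitochondrial membrane, stood at 19.1 and 17.2 FPKM in beige and was listed at 0 in both white libraries. Cidea, a lipid droplet protein of brown and beige fat, stood at 56.1 and 52.3 FPKM against 0.105 and 0, and Elovl3, a fatty acid elongase, rose to 62.7 and 73.7 FPKM from 0.243 and 0.0932 (5.89, SE 0.13, adjusted p = 4.54e-08). Markers of macrophages fell (22 of 24 lower, 1 higher, median −2.29), and Lyz2, which encodes lysozyme, went from 268 and 287 FPKM in white to 9.47 and 7.59 FPKM in beige.

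Oxidative genes rose with the thermogenic ones. Of the nuclear-encoded subunits of oxidative phosphorylation, 53 of 55 were higher and 0 lower, with Cyc1 of complex III at 251 and 230.2 against 54.4 and 53.1 FPKM. Fatty acid oxidation had 25 of 26 members higher and 1 lower, and Cpt1b, which imports fatty acids into mitochondria, stood at 74.1 ± 0.452 against 0.732 ± 0.0818 FPKM (mean ± SD, 2 libraries each, as in all such values). In the TCA cycle list 17 of 19 members were higher and 0 lower. PPARγ targets had 32 of 36 members higher and 2 lower, among them Plin5, a lipid droplet protein (3.93), and Pdk4, an inhibitor of pyruvate dehydrogenase (3.05). Of the list of hypoxia and glycolysis genes, 22 of 23 were higher and 1 lower, with the prolyl hydroxylase Egln3 at 77.3 ± 11.7 against 2.08 ± 0.327 FPKM. The adipocyte core list was divided, 22 of 35 higher and 5 lower (median 0.87, and 0.572 after quantile normalization): the fatty acid binding protein Fabp4 rose by 1.69 and the adipokine Adipoq by 0.59, while Dgat2, of triglyceride synthesis, fell by 2.71 and Cfd, the protease adipsin, fell by 3.75. Pparg itself stood at 46.0 ± 1.38 against 45.4 ± 0.573 FPKM (adjusted p = 0.88), and Lep, the adipokine leptin, fell by 3.09. Among the largest rises was also the mitochondrial protein Chchd10 (4.86), and among the largest falls were the scavenger receptor Stab1 (−4.30), Mrc1, a mannose receptor of macrophages (−4.47), the Wnt modulator Sfrp2 (−4.02) and the basement membrane protein Nid2 (−3.91). The elongin subunit Tceb2 stood at 114 and 103 FPKM in beige and was listed at 0 in both white libraries. Ppargc1a, a coactivator of mitochondrial genes, rose by 1.67 and Prdm16, a coregulator of brown fat, by 0.48. Of the control genes, Actb fell by 0.83 and Tbp differed by −0.08 (adjusted p = 0.653). Gapdh, which may share reads, was higher, at 142 and 117 FPKM in beige against 41.0 and 27.2 FPKM in white. Rplp0 stood at 184 and 177 FPKM in beige against 228 and 238 FPKM in white.

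Interferon-stimulated genes were higher in beige cultures, 52 of 62 with 2 lower (median 1.11). Rsad2, the antiviral enzyme viperin, rose by 3.88 (SE 0.19, adjusted p = 1.25e-06). Stress response lists moved the same way, with 24 of 26 integrated stress response genes higher and 1 lower, and 19 of 21 unfolded protein response genes higher and 0 lower. Ddit3, a transcription factor of both, stood at 117 ± 0.911 against 23.1 ± 8.17 FPKM. Genes of stromal cells fell. Of preadipocyte and stromal progenitor markers, 21 of 22 were lower and 0 higher, with the growth factor receptor Pdgfra at 8.07 ± 0.186 against 63.7 ± 4.41 FPKM. Of extracellular matrix genes, 40 of 45 were lower and 1 higher, and the proteoglycan Lum fell by 3.67. Wnt pathway genes (13 of 16 lower, 1 higher), cell cycle genes (23 of 30 lower, 1 higher) and endothelial markers (7 of 7 lower) also fell. After quantile normalization 13 cell cycle genes were lower and 2 higher, and their median was −0.251 against −0.572.

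The test called 6069 of 11294 genes at an adjusted p under 0.05, 2440 higher and 3629 lower in beige. The share of calls that were higher, 40.2%, was 50.9% after quantile normalization, 51.4% after median centring and 27.7% with small RNA genes left out, so the balance of directions depends on the scaling. The median log2 fold change of all genes was −0.0979, and 0.0171, 0.0109 and −0.233 under these 3 scalings. Small RNA genes took 23.9% and 24.5% of the FPKM in WT beige and 28.7% and 29.7% in WT white. By camera, a competitive gene list test, 22 of 41 lists passed, and none passed with an estimated correlation between genes, where the smallest value was an adjusted p = 0.204 with an estimated correlation. KO-labelled beige and white cultures differed in the same kind of genes, with 6887 genes called: thermogenic genes were higher for 26 of 30 (adjusted p = 0.187 with an estimated correlation), interferon-stimulated genes for 53 of 62 with 3 lower (adjusted p = 0.449 with an estimated correlation), and macrophage markers were lower for 23 of 24 with 1 higher (adjusted p = 0.197 with an estimated correlation). In them Cidea stood at 115 and 89.5 FPKM in beige and 0.0902 and 0.169 FPKM in white, and Isg15, a ubiquitin-like interferon-induced protein, rose by 2.45. Of the 6887 calls 43.7% were higher, against 52.8% after quantile normalization, 52.8% after median centring and 29.2% without small RNA genes, with medians of all genes of −0.0622, 0.0598, 0.0475 and −0.255.

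The comparison of KO-labelled with WT beige adipocytes asks whether ATF7 affects the beige programme. Few single genes passed: Cyp4b1, a cytochrome P450, rose from 10.7 and 14.2 FPKM to 37.8 and 76.7 FPKM (2.04, SE 0.28, adjusted p = 0.0358). Lars2, the mitochondrial leucyl-tRNA synthetase, fell from 54.7 and 48.0 FPKM to 14.5 and 15.6 FPKM (−1.70, SE 0.13, adjusted p = 0.00143). Also lower were the epithelial secreted protein Sbsn (−1.22), the small GTPase Rasd1 (−1.11), the alcohol dehydrogenase Adh1 (−0.95), the noncoding RNA Snhg11 (−0.78) and Mgp, an inhibitor of calcification (−0.75), with adjusted p from 0.029 to 0.0331. Rnf146, a ubiquitin ligase, was listed at 0 in both WT libraries and stood at 16.5 and 12.95 FPKM in the KO-labelled ones, and Wdr77, a methylosome subunit, was listed at 0 in WT against 6.16 and 7.35 FPKM.

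Interferon-stimulated genes lay higher as a group in KO-labelled beige cultures, with a median log2 fold change of 0.52 and 59 of 62 members above 0 (camera adjusted p = 4.61e-21, but adjusted p = 0.758 with an estimated correlation). Of these 62, 0 passed over all genes tested, and 38 were higher and 0 lower adjusted over the list alone. The estimated correlation between members of this list was 0.726, against the preset of 0.01, so the 38 are not independent of each other. Without WT beige replicate 1 the median was 0.32. Rsad2 stood at 44.2 and 40.3 against 18.8 and 24.7 FPKM (adjusted p = 0.187) and Iigp1, an interferon-induced GTPase, at 57.0 and 51.8 against 25.5 and 34.6 FPKM (adjusted p = 0.195). Thermogenic genes had a median of 0.31 with 26 of 30 above 0 (adjusted p = 2.31e-07, and adjusted p = 0.758 with an estimated correlation). None of them passed over all genes, and 9 were higher and 0 lower adjusted over the list alone. With all 12 libraries in 1 fit, without small RNA genes and without KO-labelled beige replicate 1, 1 passed in each, and 2 passed without KO-labelled beige replicate 2. Cidea stood at 115 and 89.5 against 56.1 and 52.3 FPKM (adjusted p = 0.0561), Cox8b, a cytochrome oxidase subunit of brown fat, at 282 ± 17.0 against 169 ± 18.6 FPKM (adjusted p = 0.0678), and Ucp1 at 51.6 and 24.5 against 19.1 and 17.2 FPKM (adjusted p = 0.328). Lists of fatty acid oxidation (0.25, adjusted p = 1.58e-05), the TCA cycle (0.18, 0.00151), oxidative phosphorylation (0.15, 0.00354) and MHC class I antigen processing (0.28, 0.000142) also lay higher by camera, with 0 members called in each. None of these 4 passed when the correlation was estimated, with an adjusted p = 0.758 with an estimated correlation or above. On the other side were hypoxia and glycolysis (−0.19, adjusted p = 4.36e-05), extracellular matrix (−0.10, 3.42e-05), de novo lipogenesis (−0.12, 0.00151), white-selective markers (−0.07, 0.0038) and the adipocyte core (−0.02, 0.00982), again with 0 called. After quantile normalization white-selective markers had a median of −0.148 with 1 lower, and the adipocyte core −0.0721. Extracellular matrix then had −0.164 and oxidative phosphorylation 0.0909. With an estimated correlation the smallest of all 41 was an adjusted p = 0.758 with an estimated correlation. Macrophage markers had a median of 0.05 (adjusted p = 0.637), and Pparg stood at 50.5 and 49.1 against 47.0 and 45.1 FPKM (adjusted p = 0.722). Cebpa, a transcription factor of adipocyte differentiation, differed by −0.15 (adjusted p = 0.682), the coactivator Ppargc1a by 0.40 (adjusted p = 0.366) and the control gene Actb by 0.12 (adjusted p = 0.755).

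The test called 17 of 11294 genes, 6 higher and 11 lower, with 1160 genes at an unadjusted p under 0.05, and 8 of the 17 had a library listed at 0. Among these were Rnf146 and Wdr77, whose zeros in both WT libraries may be failed estimates, which no setting tests. Without WT beige replicate 1 the count was 5, and without WT beige replicate 2 it was 11; 3 of the 9 called genes named above, Rnf146, Wdr77 and Lars2, kept their call in every setting and with each library left out.

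The same comparison in white adipocytes, cultured without rosiglitazone, gave more calls. Of macrophage markers 7 of 24 rose over all genes tested and 0 fell, and 19 were higher adjusted over the list alone (median 0.69, camera adjusted p = 9.43e-13, adjusted p = 0.472 with an estimated correlation). Fcer1g, a signalling chain of Fc receptors, rose from 21.8 ± 2.03 to 37.1 ± 0.190 FPKM (0.75, SE 0.10, adjusted p = 0.0153), and Csf1r, the receptor of the macrophage growth factor CSF1, from 12.3 ± 1.72 to 20.7 ± 1.02 FPKM (0.71, SE 0.12, adjusted p = 0.0328). In the adipocyte core 5 of 35 fell and 0 rose, and 17 lower adjusted over the list alone (median −0.38, adjusted p = 8.25e-13, adjusted p = 0.472 with an estimated correlation). Cidec, which enlarges lipid droplets, fell from 146 and 135 FPKM to 88.2 and 81.0 FPKM (−0.73, SE 0.11, adjusted p = 0.023), Cd36, a fatty acid transporter, by 0.67 and Pck1, of glyceroneogenesis, by 1.03.

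Among the largest rises were Mgl2, a macrophage lectin (1.72), and the chemokine Ccl12 (1.67, SE 0.11, adjusted p = 0.000309), and Cd72, of B cells and myeloid cells, was listed at 0 in WT and stood at 3.55 and 5.71 FPKM in KO-labelled libraries. Lcn2, the iron-siderophore carrier lipocalin 2, rose from 3.31 and 4.06 to 21.2 and 20.7 FPKM (2.23, SE 0.27, adjusted p = 0.00798), and the lactate exporter Slc16a3 by 1.51. Among the largest falls, Znhit1, a subunit of a chromatin remodelling complex, stood at 10.2 and 12.9 FPKM in WT, Slc7a10, an amino acid transporter of white adipocytes, at 8.19 and 6.11 FPKM, and the ferredoxin Fdx1l at 6.28 and 5.31 FPKM, and all 3 were listed at 0 in the KO-labelled libraries. Mup6, of a multigene family whose copies may share reads, fell by 1.71, the apolipoprotein Apoc4 by 1.31 and Cd209f, a lectin of macrophages and dendritic cells, by 1.29.

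Interferon-stimulated genes had a median of 0.47, with 5 of 62 higher and 0 lower over all genes and 35 higher and 1 lower adjusted over the list alone (adjusted p = 2.73e-13, adjusted p = 0.569 with an estimated correlation). The estimated correlation between these genes was again 0.726. Ifit3, an antiviral RNA-response protein, rose from 2.35 and 3.91 to 7.05 and 9.95 FPKM (1.21, adjusted p = 0.0339), and the nuclear body protein Sp100 rose by 0.82. In the unfolded protein response 4 of 21 fell and 0 rose (median −0.34, adjusted p = 2.04e-10, adjusted p = 0.499 with an estimated correlation): Hspa5, the main chaperone of the endoplasmic reticulum, went from 225 and 329.8 to 136 and 132 FPKM (−1.02, adjusted p = 0.0306), and Manf, Sdf2l1 and the co-chaperone Dnajb9 fell by 0.84, 0.80 and 0.58. In the integrated stress response 2 of 26 fell, Mthfd2 of mitochondrial folate metabolism and Cth of cysteine synthesis (median −0.19, adjusted p = 5.87e-05, adjusted p = 0.499 with an estimated correlation). PPARγ targets had 5 of 36 lower and 0 higher (median −0.22, adjusted p = 2.05e-07, adjusted p = 0.472 with an estimated correlation), and Fabp4, at 1964 ± 33.2 against 2776 ± 395 FPKM, missed the threshold (adjusted p = 0.158). Thermogenic genes had a median of 0.01, whose sign turned under quantile normalization and median centring, with 0 of 30 called.

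Cell cycle genes had 6 of 30 higher and 1 lower (median 0.34, adjusted p = 1.55e-07, adjusted p = 0.129 with an estimated correlation). By fry this list passed (fry adjusted p = 0.000139). The centromeric histone Cenpa rose from 1.16 and 1.06 to 2.48 and 2.58 FPKM (0.74, adjusted p = 0.0153). The mitotic genes Cdc20 and Kif20a were listed at 0 in WT and stood at 1.80 and 2.39 FPKM and at 1.47 and 1.74 FPKM in KO-labelled libraries, and the replication factor Gins2, at 3.17 and 2.79 FPKM in WT, was listed at 0 in the KO-labelled libraries. Replication-dependent histones, whose near-identical copies may share reads, had 3 of 26 higher and 0 lower (median 0.56, adjusted p = 1.81e-08, adjusted p = 0.18 with an estimated correlation). In de novo lipogenesis 3 of 20 rose and 0 fell (median 0.13, adjusted p = 0.0297, adjusted p = 0.499 with an estimated correlation): Thrsp, a lipogenic nuclear protein (35.4 and 49.7 to 107 and 111 FPKM), Acly, which makes cytosolic acetyl-CoA (1.01), and the acetyl-CoA carboxylase Acaca (0.53). Txnip, a thioredoxin inhibitor that limits glucose uptake, rose from 39.5 and 41.2 to 109 and 115 FPKM (1.45, SE 0.10, adjusted p = 0.000341). Preadipocyte markers had a median of 0.19 (adjusted p = 0.0186, adjusted p = 0.472 with an estimated correlation), with Pi16 higher by 0.70. In the matrix list, which did not pass (median 0.103, camera adjusted p = 0.671), Col14a1 rose by 0.74.

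The test called 213 genes, 143 higher and 70 lower, with 2246 at an unadjusted p under 0.05, and 14 of the calls had a library at 0. The count fell without WT white replicate 2 and without either KO-labelled white replicate. Fewer macrophage, adipocyte core, interferon-stimulated, unfolded protein response and cell cycle genes were called in these 3 settings, although the medians of the first 4 lists kept their sign. Each setting leaves a group with 1 library, which lowers the power of the test. Whether the calls rested on single libraries was therefore not told apart from lost power. Without WT white replicate 1, 0 interferon-stimulated genes were called, and 2 genes of the unfolded protein response, whose median was then −0.565. The interferon-stimulated median was 0.285 without KO-labelled white replicate 2. With all libraries kept, the genes called ran from 0 (no filter) to 16 (all 12 libraries in 1 fit) for interferon-stimulated genes and from 0 (no filter) to 8 (quantile normalization) for the unfolded protein response. They ran from 1 (no filter) to 11 (quantile normalization) for the adipocyte core, from 1 (pseudocount of 0.1) to 16 (all 12 libraries) for macrophage markers and from 3 (pseudocount of 0.1) to 8 (all 12 libraries) for cell cycle genes, and PPARγ targets had 10 lower after quantile normalization. The share of calls that were higher, 67.1%, was 50.4% after quantile normalization and 52.8% after median centring. Of the 42 called genes taken up by the naming rule, Txnip, Znhit1, Slc7a10 and Fdx1l kept their call in every setting. Of these Znhit1, Slc7a10 and Fdx1l were listed at 0 in both KO-labelled libraries, and no setting tests whether such zeros are failed estimates. A further 5 (Cd72, Mup6, Cdc20, Kif20a and Gins2) did not pass the filter, and so were not tested, without 1 or the other library of a group.

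**Figure D2:**
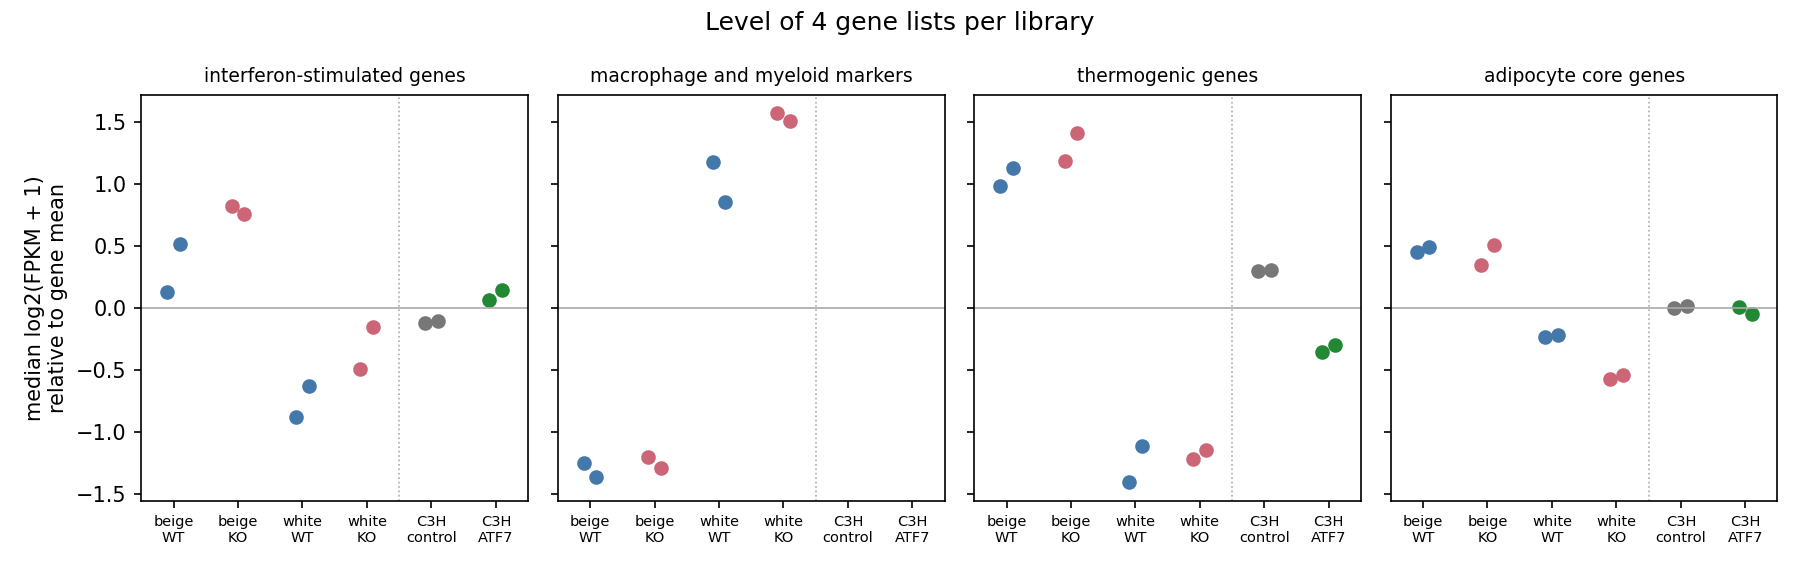
Median of log2(FPKM + 1), relative to each gene's mean within its fit, over the members of 4 gene lists in each library. Points are libraries. C3H10T1/2 libraries have no point for macrophage markers, of which 1 member was tested there.

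Whether the KO effect differed between beige and white cultures was tested as an interaction. It passed for 33 genes, 12 with a more positive effect in beige and 21 with a more negative one, and 20 of the 33 had a library at 0. Without WT beige replicate 1 the count was 16, and without KO-labelled white replicate 2 it was 19. Txnip differed by −1.35 and Lars2 by −2.66 (beige minus white), since Lars2 rose by 0.96 in KO-labelled white cultures and fell in beige ones. Across 11294 genes the KO effects in beige and white had a Spearman's rho of −0.116, which was 0.0171 without KO-labelled beige replicate 2 and −0.175 without KO-labelled beige replicate 1. Among the calls, Cntfr, a cytokine receptor, was higher in both cultures and B3galt2, Mgp and Sbsn were lower in both, against 0.076 and 0.0682 shared genes if the calls were independent. These 4 shared genes were named after their values were seen.

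Overexpression of ATF7 in C3H10T1/2 beige adipocytes is the opposite manipulation of the gene and asks whether more ATF7 changes the beige programme. Of thermogenic genes 15 of 28 fell and 0 rose over all genes tested, and 25 were lower and 2 higher adjusted over the list alone (median −0.62, camera adjusted p = 2.29e-20, adjusted p = 0.317 with an estimated correlation). The estimated correlation of this list, −0.00276, lay below the preset of 0.01, and by fry the list passed (fry adjusted p = 0.00969). Ucp1 (chromosome 8, 83290348 to 83298456) fell from 8.71 and 6.82 FPKM to 1.08 and 0.820 FPKM (−2.16, SE 0.13, adjusted p = 0.00198). Cidea fell from 96.4 and 84.7 to 24.8 and 25.95 FPKM (−1.79, SE 0.08, adjusted p = 0.000472), Cpt1b by 1.53 and Elovl3 by 1.51. Members of the adipocyte core list were divided: Car3, Pck1 and Dgat2 fell, while Pparg stood at 53.4 ± 0.831 against 54.5 ± 2.83 FPKM (adjusted p = 0.875), Fabp4 at 9352 ± 603 against 9366 ± 57.8 FPKM (adjusted p = 0.99) and Adipoq at 1164 ± 43.8 against 1061 ± 28.1 FPKM (adjusted p = 0.445).

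Fatty acid oxidation had 6 of 26 lower and 0 higher (median −0.24, adjusted p = 2.06e-10, adjusted p = 0.489 with an estimated correlation), with Ehhadh of peroxisomal oxidation down from 43.2 ± 1.48 to 26.1 ± 1.49 FPKM, the thiolase Acaa2 from 311 ± 12.9 to 198 ± 8.12 FPKM and Hadhb, of the trifunctional protein, by 0.54. Oxidative phosphorylation (median −0.19, adjusted p = 2.06e-10, adjusted p = 0.489 with an estimated correlation) and the TCA cycle (−0.21, adjusted p = 4.86e-06, adjusted p = 0.502 with an estimated correlation) had 0 members called over all genes, and each had 11 lower adjusted over the list alone, with 0 and 1 higher. PPARγ targets had 8 of 37 lower and 1 higher (median −0.07, adjusted p = 0.00344, adjusted p = 0.489 with an estimated correlation). Hypoxia and glycolysis had 2 of 22 lower, the glycolytic enzyme Eno1 (−0.87) and Pfkfb3, which stimulates glycolysis (−0.61), with a list median of −0.33 (adjusted p = 4.86e-06, adjusted p = 0.669 with an estimated correlation). Car3, a carbonic anhydrase abundant in adipocytes and a member of the adipocyte core list, fell from 106 and 115 to 26.4 and 28.1 FPKM (−1.98, SE 0.07, adjusted p = 0.000218), and the retinoid-binding protein Rbp7 fell by 1.85. The adipocyte core had 3 of 35 lower and 1 higher, with a median of −0.03 (adjusted p = 0.433) that turned to 0.01 without small RNA genes. Pck1 fell by 0.52 and Dgat2 by 0.43, and Cfd rose by 0.65.

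Among the rises were the membrane protein Pdzk1ip1 (2.79 and 2.78 to 7.50 and 8.11 FPKM, adjusted p = 0.00263), Cystm1 (1.07), the chemokine Ccl9 (1.01) and the ether lipid enzyme Agmo (0.92), and Morn2 was listed at 0 in the controls and stood at 5.10 and 2.63 FPKM. The transcript of the Gt(ROSA)26Sor locus, the mitochondrial ribosomal protein gene Mrpl48 and Pdss1, of ubiquinone synthesis, stood at 4.03 to 8.61 FPKM in the controls and were listed at 0 in both overexpressing libraries. Cholesterol synthesis genes had a median of 0.15, with 1 of 24 higher, the sterol carrier Stard4 (0.56), and 0 lower (adjusted p = 2.23e-07, adjusted p = 0.489 with an estimated correlation). The desaturases Fads1 and Fads2 rose by 0.55 and 0.61 and Scd1 fell by 0.57, in a lipogenesis list with 2 of 20 higher and 1 lower (adjusted p = 0.263). Interferon-stimulated genes had 2 of 27 higher and 0 lower (median 0.20, adjusted p = 9.72e-06, adjusted p = 0.489 with an estimated correlation), namely Gbp2 (0.54) and Ifit1 (0.92). With any of the 4 libraries left out 0 of them were called, and without overexpressing replicate 2 the median was 0.0588. Of MHC class I genes 2 of 16 rose, H2-K1 (8.39 and 8.59 to 17.7 and 15.9 FPKM) and H2-D1 (0.76), paralogues that may share reads, with a list median of 0.17 (adjusted p = 0.000583, adjusted p = 0.489 with an estimated correlation). Extracellular matrix genes had 1 of 41 lower, Thbs2, a thrombospondin (−0.87), and a median of −0.13 (adjusted p = 0.0217, adjusted p = 0.489 with an estimated correlation), with 0 lower after quantile normalization.

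The test called 149 of 9981 genes, 43 higher and 106 lower, with 1715 at an unadjusted p under 0.05, from 2 residual degrees of freedom. The count was 17 without overexpressing replicate 1 and 29 without overexpressing replicate 2, with 4 and 5 thermogenic genes called and 1 gene of fatty acid oxidation in each. Without control replicate 1 or 2, 2 and 3 genes of fatty acid oxidation were called. Without a filter, 4 thermogenic genes, 1 gene of fatty acid oxidation and 0 interferon-stimulated genes were called. The share of calls that were higher was 28.9%, and 45.2% with small RNA genes left out, whose share of the FPKM was 31.5% and 27.5% in the overexpressing libraries and 27.1% and 25.2% in the controls. Of the 37 called genes taken up by the naming rule besides Atf7, Ucp1, Cidea, Cpt1b, Car3 and Pdzk1ip1 kept their call in every setting, while 5 (Morn2, Gt(ROSA)26Sor, Mrpl48, Pdss1 and Ifit1) did not pass the filter, and so were not tested, in at least 1 setting with a library left out.

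Effects of the KO label in beige cultures and of overexpression in C3H10T1/2 had a Spearman's rho of −0.0451 across 9700 genes (−0.00161 without overexpressing replicate 2 and −0.0912 without overexpressing replicate 1). Pearson's r over the same genes was 0.0388, so the sign depends on the measure. Calls in opposite directions were shared by 0 genes, against 0.04 and 0.038 if independent. Of the 97 genes lower with overexpression among those tested in both fits, 69 (71.1%) had a positive log2 fold change in KO-labelled beige cultures, against 62.8% of all genes. Of the 41 genes higher with overexpression and tested in both fits, 27 (65.9%) had a negative one, against 37% of all genes. Cidea was lower with overexpression and stood at 102 ± 17.9 against 54.2 ± 2.70 FPKM in KO-labelled beige cultures, where it missed the threshold. The cultures differ in origin, and no test of the difference between them was made.

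**Figure D3:**
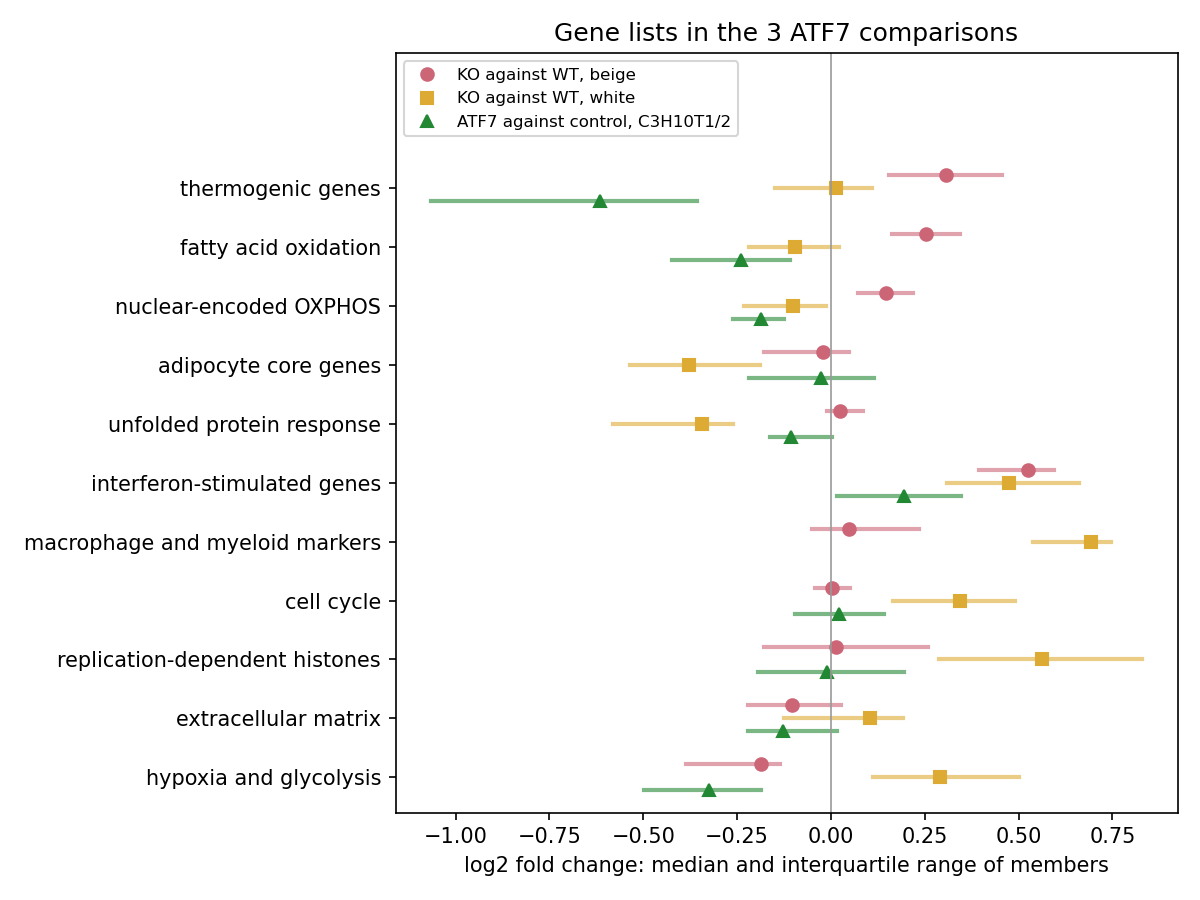
Log2 fold changes of 11 gene lists in the 3 comparisons of ATF7 genotype or dose. Points are the median over a list's tested members and lines span the middle quartiles. The thermogenic list has a median of −0.62 with overexpression and 0.31 in KO-labelled beige cultures.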

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

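The tests of the thermogenic and myeloid patterns were chosen after the results were seen; that of genes listed at 0 was not.

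The effect of the KO label differed between beige and white cultures for 33 genes by the interaction test in limma. Differences are given as beige minus white on the log2 scale. Genes with a more positive effect in beige were Rnf146 (4.34), Znhit1 (3.67), Fdx1l (3.25), Wdr77 (3.17), Slc7a10 (2.6), Gins2 (1.99), Mup6 (1.71) and Cox8b (1.05). Genes with a more negative effect were Lars2 (−2.66), Cd72 (−2.47), Ccl12 (−2.46), Cdc20 (−1.62), Hist1h3i (−1.43), Kif20a (−1.38), Txnip (−1.35), Acly (−1.28) and Cenpa (−1.04). Rnf146, Wdr77, Znhit1, Fdx1l, Slc7a10, Gins2, Mup6, Cd72, Cdc20 and Kif20a were listed at 0 in whole groups, so their fitted differences depend on the pseudocount. For Mup6, Gins2, Cdc20 and Kif20a the difference has the size of the effect in white alone, so none was seen in beige. A gene hardly expressed in beige could show none on this scale.

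By camera the KO effect on 19 of 41 lists differed between the cultures, and 0 differed with an estimated correlation, where the smallest was an adjusted p = 0.164 with an estimated correlation. Lists with a more positive median effect in beige were the unfolded protein response (0.398), PPARγ targets (0.345), skeletal muscle genes (0.326), adipocyte core genes (0.324), thermogenic genes (0.308), oxidative phosphorylation (0.265), fatty acid oxidation (0.254), the integrated stress response (0.254), the TCA cycle (0.227) and MHC class I (0.187). Lists with a more negative median effect were replication-dependent histones (−0.665), hypoxia and glycolysis (−0.574), macrophage markers (−0.567), cell cycle (−0.32), preadipocyte markers (−0.227), lipogenesis (−0.182), extracellular matrix (−0.138), Wnt (−0.134) and NF-κB (−0.0991). Macrophage markers stood lower in WT beige than in WT white (median −2.285), and the log2(FPKM + 1) scale understates the change of low genes. After quantile normalization lipogenesis had −0.282 and extracellular matrix −0.228. Without small RNA genes NF-κB had −0.153 and MHC class I 0.119.

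Of 28 thermogenic genes, 15 were lower with ATF7 overexpressed in C3H10T1/2, and 4 or 5 without overexpressing replicate 1 or 2, and 4 of 37 without a filter. A smaller share of cells in the adipocyte state would lower other adipocyte genes alike, and the 24 adipocyte core genes outside the thermogenic and PPARγ lists had a median of −0.0718 (median absolute deviation 0.191), against −0.616 (0.321) for thermogenic genes. Scaling is argued against as well, since at least 14 thermogenic genes were lower under each of 3 other scalings. A response to ATF7, a difference between the cultures and an effect of the expression construct were not tested against each other and stay open.

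Of 24 macrophage markers, 7 were higher in KO-labelled white cultures (median 0.694), and 0 without WT white replicate 2 or either KO-labelled white replicate. A lower share of adipocytes would raise other cell types alike. The 73 preadipocyte, matrix and endothelial markers had a median of 0.133 (median absolute deviation 0.168, and 0.103 for macrophage markers). Of these 73, 45 were matrix genes, which need not mark other cell types. Preadipocyte markers had 0.194, endothelial markers 0.173 and the adipocyte core −0.378. These markers rose less than macrophage markers, but a lower share of adipocytes as a part of the rise is not excluded. A further list of 35 macrophage genes had a median of 0.562, with 32 above 0 and Vsig4, Lyve1 and Cbr2 below, as a larger macrophage share would give. A larger share of unchanged make-up is argued against by 5 of 15 abundant genes more than 2 SE below the list median: Lyz2, Ctss, F13a1, Cbr2 and Gas6, of which Cbr2 and Gas6 are also expressed in C3H10T1/2, and which were chosen after their values were seen. A larger share together with a change of state may remain, and so may an effect of the genotype, since neither was separated here.

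Several genes were listed at 0 in both libraries of a group and well above 0 in the other group, among them Rnf146, Znhit1 and Mrpl48. Failed estimates may be the cause: in 76 replicate pairs 1 library was at 0 and the other at 5 FPKM or more, against 65 pairs with both at 0 among genes at that level elsewhere. A loss of expression in these groups was not tested in another way, and such genes are better read from reads, which were not analysed here.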

How the results depend on the processing

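Alternatives that left out small RNA genes, and quantile normalization for the agreement of effects, were tests chosen after the data were seen. Of 146 called genes taken up by the naming rule, 85 kept their call in every setting that kept all libraries and 68 also with each library left out, where a gene that no longer passed the filter counts as not kept. Of the 146, 0 changed sign where they were tested, but the rule favours large and clear changes. Among all calls of beige against white, 20 of 6069 in WT and 121 of 6887 in KO-labelled cultures had the opposite sign after quantile normalization. Most of the 85 came from beige against white, 51 of 51 in WT and 6 of 7 in KO-labelled cultures. For the KO label they were 3 of 9 in beige and 18 of 42 in white, and 7 of 37 with overexpression. With each library also left out, fewer kept their call in white and with overexpression, as named above. Alternatives meant for counts were not run because the values were FPKM. Depth is unknown, so what it limits could not be measured.

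For KO-labelled against WT beige, the 17 genes became 26 with all 12 libraries in 1 fit. For white, 213 became 54 with a pseudocount of 0.1, 122 without a filter, 387 after quantile normalization, 642 with all 12 libraries, 344 without small RNA genes and 116 with only the groups compared. For the interaction, 33 became 20 with a pseudocount of 0.1 and 116 with all 12 libraries. For overexpression, 149 became 22 without a filter, 91 without a trend and 116 with all 12 libraries. The cause was not tested.

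Labels give groups the same replicate numbers, and replicate differences correlated across genes between groups at −0.0962 to 0.151. The value was 0.134 between WT and KO-labelled beige, 0.151 between WT and KO-labelled white, and 0.0876 between control and overexpressing libraries. Between beige and white groups it ran from −0.0962 to −0.00585. Pairing within a culture is therefore not excluded. In primary cultures it was not tested, since the replicate block held 1 term for beige and white together. With a replicate block the counts were 27, 225, 35 and 88 for beige, white, interaction and overexpression. In that fit 2 thermogenic genes were called in beige, 13 interferon-stimulated genes in white, and 3 genes of fatty acid oxidation and 0 interferon-stimulated genes with overexpression.

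With each library left out in turn, the counts ran from 5 to 20 for beige, from 23 to 277 for white, from 16 to 43 for the interaction and from 17 to 138 for overexpression, and from 4717 to 5409 and 5560 to 6404 for beige against white in WT and KO-labelled cultures. The lowest counts came without WT beige replicate 1 (5, and 16 for the interaction), without KO-labelled white replicate 2 (23, and 19 for the interaction) or 1 (25), without WT white replicate 2 (43), and without overexpressing replicate 1 (17) or 2 (29); without WT beige replicate 2 the count for beige was 11. The log2 fold change of Atf7 ran from −0.0933 (without KO-labelled beige replicate 2) to 0.0203 (without replicate 1) in beige and from −0.284 (without WT white replicate 2) to 0.0336 (without WT white replicate 1) in white, where it was not called. The agreement of KO effects ran from −0.175 to 0.0171, and that of KO and overexpression from −0.0912 to −0.00161, with −0.0834 among genes of at least 10 FPKM. The cause was not tested.

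With an estimated correlation, 0 lists passed in beige, white, the interaction, overexpression and both comparisons of beige with white. In this setting camera uses only the residual degrees of freedom, 4 in primary cultures and 2 in C3H10T1/2. For cell cycle genes in white the estimated correlation was −0.023, below the preset of 0.01, yet the camera p went from 2.265e-08 to 0.00315. In primary cultures the estimated correlation was 0.726 for interferon-stimulated genes, 0.744 for hypoxia and glycolysis, 0.709 for fatty acid oxidation and 0.688 for the unfolded protein response. Thermogenic genes in WT beige against white also missed, with 26 of 30 higher, so a miss in this test does not show that a list was unchanged. By fry, a test that does not compare a list with other genes, 0, 8, 3 and 1 lists passed in beige, white, the interaction and overexpression, against 11, 16, 19 and 14 by camera. In white these were cell cycle, replication-dependent histones, macrophage markers, the adipocyte core, white-selective markers, lipogenesis, osteogenic genes and skeletal muscle genes. In the interaction they were cell cycle, skeletal muscle genes and lipogenesis, and with overexpression thermogenic genes. Interferon-stimulated genes passed by fry in none of these comparisons. Beige against white went the other way, with 30 by fry against 22 by camera in WT and 33 against 23 in KO-labelled cultures.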

Other observations

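The tests of carbohydrate-response genes and of variation between replicates were chosen after the results were seen, but the test of the segment around Atf7 was not.

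Genes with the same direction in both KO-labelled cultures, at an unadjusted p under 0.05 in each by limma, numbered 194, of which 125 were higher and 69 lower, against 125.1 expected if the comparisons were independent. Interferon-stimulated genes made up 32 of them, all higher, and 0 of the 119 genes with opposite directions, of which 105.6 were expected. The interferon-induced GTPase Iigp1 differed by 0.85 in beige and 0.83 in white, and the adipokine Retn by −0.80 and −0.47. Mgp differed by −0.75 and −0.88, and Lcn2 by 1.47 and 2.23. These genes were chosen after their values were seen.

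The remaining lists are given by their medians in KO-labelled against WT white cultures, where none passed by camera: ATF2 and CREB relatives −0.02, H3K9 methyltransferases 0.10, early adipogenic regulators 0.12, beige-selective markers 0.06, cholesterol synthesis −0.07, NF-κB 0.10, TGF-β 0.02, NRF2 −0.02, heat shock −0.07, immediate early genes 0.03, osteogenic genes 0.29, chondrogenic genes 0.36 and skeletal muscle genes −0.14. Endothelial markers had 0.17, pericyte markers 0.11, Schwann cell markers 0.13, housekeeping controls −0.07, ribosomal proteins 0.01, Hox genes 0.12, protocadherins 0.04 and adipokines 0.02. MHC class I had 0.103 and the TCA cycle −0.0068. The signs of TGF-β, adipokines, protocadherins, ribosomal proteins and the TCA cycle turned under at least 1 other scaling. The lists of p53 (−0.15, adjusted p = 0.0308), Wnt (0.15, adjusted p = 0.0492), oxidative phosphorylation (−0.10, adjusted p = 0.000794), fatty acid oxidation (−0.10, adjusted p = 0.0492), white-selective markers (−0.21, adjusted p = 0.00115) and hypoxia with glycolysis (0.29, adjusted p = 0.0186) passed by camera. With a replicate block Wnt no longer passed by camera (adjusted p = 0.0504). The smallest value over all 41 lists was an adjusted p = 0.129 with an estimated correlation. With overexpression, ribosomal proteins (0.07, adjusted p = 0.0123), NRF2 (0.03), Wnt (−0.15) and osteogenic genes (−0.31, each with adjusted p = 0.0496) passed by camera, where the smallest over all 38 lists was an adjusted p = 0.317 with an estimated correlation. With a replicate block NRF2, Wnt and osteogenic genes no longer passed by camera (adjusted p = 0.0547, 0.0566 and 0.0545). In primary cultures 0 mitochondrially encoded, lymphoid and erythroid genes were tested, 1 epithelial gene (Krt19, 0.43 in white, adjusted p = 0.375) and 2 mesothelial genes (Krt19 and Aldh1a2, −0.03).

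A segment from another strain beside Atf7 would place genes with the same direction in both KO-labelled cultures near it. Of the 194, 2 lay within 20 Mb of Atf7, where 164 genes were tested, an odds ratio of 0.703 (95% interval 0.0838 to 2.62, Fisher's exact test, two-sided, p = 1), which argues against such a segment as a source of many of these genes.

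Txnip, Thrsp and Acly were higher in KO-labelled white cultures, and a wider response to carbohydrate was considered as a candidate explanation. The other 15 members of a list of such genes had a median of 0.163, 10 of them above 0 (median absolute deviation 0.224), with a camera p of 0.0942, and 0.191 with an estimated correlation. These values lie between the bounds set, so the question stays open.

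Interferon-stimulated genes had medians of 0.525 in KO-labelled against WT beige and 0.474 in white cultures, and of 0.32 without WT beige replicate 1 and 0.285 without KO-labelled white replicate 2. Variation between replicates of a group could give such a difference: replicates of WT beige differed by 0.368 in the median of the list, those of WT white by 0.275, of KO-labelled white by 0.353 and of KO-labelled beige by −0.0932. The labels do not say whether replicates were separate cultures, so variation between cultures may be larger than these values. With 2 libraries per group, the genotype and variation between cultures cannot be told apart for this list.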
